A study of Danio rerio with 4 samples.

How the data were processed

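RNA from manually dissected hearts of 72 hpf zebrafish embryos was hybridised to 4 single-colour (Cy3) Agilent arrays, 2 for WT and 2 for ccm2 m201 mutants. Per the labels' protocols, 200 ng of total RNA with an RNA integrity number above 8 was amplified and labelled for each sample. Samples were grouped by their titles. The authors' deposited intensity values are processed signals from Agilent Feature Extraction 10.5.1.1, per the file headers: background-subtracted and detrended within each array, with surrogate values for dim spots and without control spots. Although deposited as normalized, the intensity columns were not scaled between arrays, because the 75th percentile of each column matched that in the array's header. The series value table held the same intensity in all 43803 features. A deposited table of raw median signal was used in 1 alternative. The deposited header file gave quality statistics (other values). In it, the barcode cells of the 2 mutant arrays are exchanged against their block names; the blocks were matched by name, and both arrays belong to the same group. Raw median signals were 35, 34.5, 35 and 34.5, and spike-in medians 251, 163, 225 and 118, on WT 1, WT 2, mutant 1 and mutant 2.

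The 43803 features hold 43603 probes; 50 probes were printed more than once and their spots were averaged on the log2 scale. The platform annotation gave 1 gene symbol for 21061 features, several for 0 and none for 22742, which are unnamed here. Symbols were updated through gene identifiers for 20133 features and through accessions for 409, and 519 kept the platform's symbol, giving 14434 symbols. Since the array design and the reference annotation use different genome builds, no coordinates are given.

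Log2 processed signals were reduced by each array's 75th percentile and raised by a common constant. The deposited tables hold neither flags nor control spots, so a probe was tested when it lay above the 40th percentile of its array on at least 2 of the 4 arrays, as planned for that case. This kept 26825 probes, 16555 of them named. Each probe was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, residual df 2, prior df 1.97), two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. A gene was counted through its probe with the highest mean signal. The header gives how many features were well above background on each array but not which, so a feature was taken as well above background when its rank was within that number (23634, 24477, 24100 and 24395 features on WT 1, WT 2, mutant 1 and mutant 2). Where no array of a group reached that signal, the fold is a lower bound: the brighter group's mean against the dimmer group's mean of, per array, the higher of that signal and the probe's own.

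The 30 gene lists were fixed before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry, for lists with at least 5 tested members. camera passed 11 lists (3 higher, 8 lower), camera with an estimated correlation 0, and fry 13 (8 higher, 5 lower). fry's test for changes in either direction passed 28 lists. camera compares a list with the other tested genes, whereas fry tests the list by itself, so their results answer different questions. The counts cover all 30 lists, of which 29 are described. Named genes were chosen by a rule fixed at the same time: ccm2, tested CCM complex genes, klf2a, klf2b and egfl7; the 10 largest rises and 10 largest falls among passing genes with non-overlapping arrays, leaving out clone names; up to 2 passing rises and 2 falls of each list, or the 2 smallest p where none passed; and the 2 brightest members of each other-cell list. With 2 arrays against 2, chance alone separates the groups in 33.3% of probes.

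The fit was tested on simulated data for this comparison, with 26825 probes. With 200 changed probes, 50 at each size, 0% were recovered at log2 changes of 1, 2 and 3 and 36% at 4, although 66%, 96%, 94% and 98% had an unadjusted p under 0.05, with 1 false call among 26625 unchanged probes. With 1 in 3 probes changed, 48.7% were recovered at a log2 change of 1, 85.9% at 2, 95.03% at 3 and 96.2% at 4, and 3.30% of calls were false. These sizes were drawn in about equal numbers, with none smaller. That setting gave 7515 calls, against 4294 changed probes in the data, so its recovery can exceed that in the data. A simulated list of 24 genes raised by 1 passed with the preset correlation and had an adjusted p of 0.294 with the estimated one. A list that does not pass with the estimated correlation can thus still be shifted. The alternatives covered normalization, background, filters, a floor, the variance model, the sample number as a block, left-out arrays, probe averaging and the threshold. Figures were drawn with matplotlib 3.10.9.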

Results

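Gene expression was measured in hearts dissected from zebrafish embryos at 72 hours post fertilization (hpf), in wild-type (WT) embryos and in ccm2 m201 mutants. Ccm2 is a scaffold protein of the cerebral cavernous malformation (CCM) complex, which acts in endothelial and endocardial cells. Each group had 2 samples, and each sample was a pool of hearts on 1 single-colour array, with all 4 arrays on 1 slide. The comparison addressed which cardiac genes depend on Ccm2. The labels do not say that the pools came from separate clutches, so p-values of single genes measure only the spread between these samples. The p-values of camera with the preset correlation rest on the spread between genes, taken as nearly independent, and do not measure replication. The description of both mutant samples also mentions overexpression of Bmp2b, whereas their titles, sources and genotypes name only the ccm2 mutation, and the labels do not settle which holds. Between 54.0% and 55.9% of the 43803 features on an array were well above background, and no feature was saturated. The number of arrays, 2 per group, limits the precision of each value below.

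Across 26825 tested probes, the log2 signals of the WT arrays correlated at r = 0.973 and those of the mutant arrays at r = 0.975, whereas the 4 pairs of a WT and a mutant array gave r between 0.915 and 0.924. These are correlations across probes, which are not independent replicates.

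The hearts of ccm2 mutants differed from WT hearts in 1975 of 11526 tested genes (17.1%), of which 934 were higher and 1041 lower in mutants. At least 2-fold changes made up 1828 of them, 864 higher and 964 lower. In 164 of the higher genes the WT signal was not well above background, and in 237 of the lower genes the mutant signal was not, so that their fold is given below only as a bound. The count fell whichever array was left out: limma called 0 genes without mutant replicate 1 and 0 without mutant replicate 2, with 8395 and 9067 of the probes at an unadjusted p under 0.05, and 567 without WT replicate 1 and 237 without WT replicate 2, with 6367 and 6354 such probes, against 9079 with all arrays. It was 874 with the sample number as a replicate block. Median scaling gave 1139 higher and 817 lower genes, and the unscaled deposited values gave 1295 higher and 770 lower. These scalings moved the median log2 difference of all genes from -0.04 to 0.11 and 0.17, and directions are given relative to the scaling at the 75th percentile.

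The transcript of ccm2 itself lay at a log2 signal of 5.62 ± 0.24 (SD, n = 2) in WT and 5.04 ± 0.17 (SD, n = 2) in mutants, a log2 difference of -0.58 ± 0.22 (SE) that did not pass the test (limma adjusted p = 0.167). The second ccm2 probe gave a log2 difference of -0.47. Of the 14 tested genes for CCM proteins and their binding partners, 2 rose, 0 fell and 12 did not pass, and the counts were the same adjusted over the list alone. krit1, which encodes the Ccm2-binding protein Krit1, rose by 1.77 ± 0.19 (SE) on the log2 scale (adjusted p = 0.0158). Its other detected probes gave 1.66 and 1.26, and 1 of them was called. heg1, which encodes a transmembrane receptor of the complex, rose by 1.77 ± 0.23 (SE, adjusted p = 0.0229). The difference for pdcd10a was 0.12 ± 0.17 (SE, adjusted p = 0.681). The list as a whole did not pass (camera adjusted p = 0.0540), and its adjusted p was 0.670 with an estimated correlation. It passed camera with median scaling (adjusted p = 0.0465), the unscaled deposited values (0.0470), no filter (0.0215), the stricter filter described below (0.0175) and normexp on raw median signal (0.0176). By fry, which does not compare it with other genes, it passed at an adjusted p of 0.0266.

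The transcription factor genes klf2a and klf2b, which respond to blood flow in endothelium, were both higher in mutant hearts. klf2a rose by 1.43 ± 0.18 on the log2 scale (SE, adjusted p = 0.0211), a 2.70-fold difference, and klf2b by 1.69 ± 0.20 (SE, adjusted p = 0.0180), a 3.23-fold difference. The second klf2b probe gave 0.86 and was not called. egfl7, which encodes a secreted endothelial protein, rose from 12.97 to 14.17 in log2 signal (SE of the difference 0.17, adjusted p = 0.0264). Each of these 3 genes lay higher on both mutant arrays than on either WT array. Among 25 tested genes for KLF2 and KLF4 factors and for responses to flow, 9 rose, 3 fell and 13 did not pass; adjusted over the list alone, 9 rose and 4 fell. wnt9b, a Wnt ligand gene, had the largest rise in this list at 4.79 ± 0.20 (SE), with 1 of the 2 WT arrays well above background. egr1, an immediate early gene, fell by 3.51 and vcam1b, an adhesion molecule gene, fell by 2.80 on the log2 scale. With members moving both ways, the list did not pass camera (adjusted p = 0.170, and adjusted p = 0.670 with an estimated correlation). It passed fry upward (adjusted p = 0.0266), which does not compare it with other genes.

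**Figure D1:**
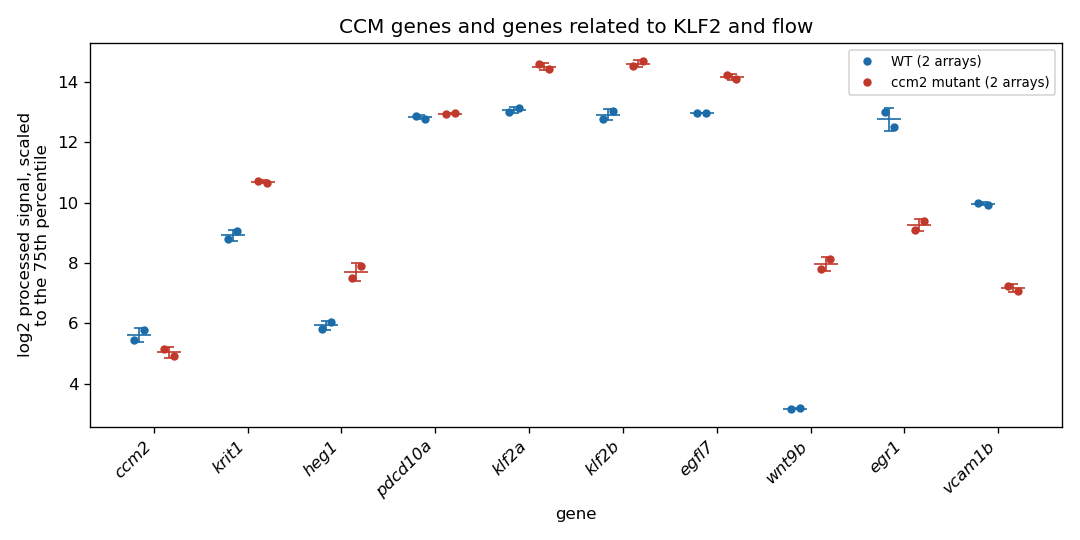
Log2 processed signal, scaled to the 75th percentile of each array, for 10 genes named in the text (vertical axis) in WT (blue) and ccm2 mutant (red) hearts; points are arrays, bars the mean and whiskers the SD of 2 arrays. klf2a, klf2b and egfl7 lie higher on both mutant arrays, and egr1 and vcam1b lower.

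Endothelial and endocardial markers were higher in mutant hearts as a group. Of 26 tested markers, 8 rose, 0 fell and 18 did not pass, and 12 rose and 1 fell adjusted over the list alone. The median log2 difference was 0.62 (camera adjusted p = 0.000437), and the adjusted p was 0.670 with an estimated correlation. aqp8a.1, a water channel gene, rose by 3.49 ± 0.19 (SE) and lmo2, a transcription cofactor of endothelial and blood cells, by 1.64 ± 0.17 (SE). Leukocyte markers moved the same way and further, with a median of 1.94, and red blood cell and smooth muscle markers the other way, with medians of -2.95 and -1.14. Genes of blood vessel growth moved both ways, with 14 of 35 higher and 8 lower (15 and 13 adjusted over the list alone; camera adjusted p = 0.464, fry upward with adjusted p = 0.0350). Among them angpt2b, which encodes an angiopoietin, was at least 13.6-fold higher in mutants, where WT signal was not well above background, and ccn2b fell by 4.72 on the log2 scale.

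Genes of BMP and TGF-beta signalling and of endothelial to mesenchymal transition were shifted upward, with 7 of 40 higher, 1 lower and 32 not past the test, and the same counts adjusted over the list alone (median 0.25, camera adjusted p = 0.0405). The mention of Bmp2b overexpression in the description of the mutant samples bears on this list and is not settled by the labels. The adjusted p was 0.133 without WT replicate 1, 0.0559 without mutant replicate 2, 0.0586 with the filter by rank above background and 0.670 with an estimated correlation. The homeobox gene msx1b rose by 2.91 ± 0.22 (SE) and tgfb1a, a growth factor gene, by 2.15 ± 0.30 (SE). Of 27 Notch pathway genes, 2 rose and 5 fell (2 and 11 adjusted over the list alone), among them hey2, a transcriptional repressor gene, which fell by 2.28, and lfng, a glycosyltransferase gene, which rose by 1.48 ± 0.17 (SE). The Notch list did not pass (camera adjusted p = 0.0617), and its adjusted p was 0.0272 without WT replicate 1, 0.0219 without mutant replicate 1, 0.0185 under the stricter filter and 0.0421 with normexp on raw median signal, over a range of 0.0185 to 0.679 among the alternatives. Of 24 Wnt pathway genes, 2 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.721), with dkk1b, a secreted Wnt inhibitor gene, higher by 4.99 ± 0.18 (SE).

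Genes of the atrioventricular canal and valves moved in both directions, with 3 of 21 higher and 4 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.721). The median of this list was 0.12 and its mean -0.12. spp1, which encodes osteopontin, fell by 7.88 on the log2 scale, with 1 of the 2 mutant arrays well above background, and all 3 of its probes gave a fall. hapln1a, which encodes a hyaluronan link protein, rose by 4.19 ± 0.21 (SE), and its second probe gave 4.29. Of 12 genes for ADAMTS proteases and hyaluronan, 4 rose and 2 fell (5 and 2 adjusted over the list alone; median 0.21, or -0.04 with dim genes at their bound; camera adjusted p = 0.560). Among 41 integrin and matrix genes 9 rose and 5 fell (13 and 8 adjusted over the list alone; camera adjusted p = 0.536, fry upward with adjusted p = 0.0338).

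Cardiomyocyte genes were lower in mutants as a group, with 0 of 31 higher, 6 lower and 25 not past the test, and the same counts adjusted over the list alone (median -0.38, camera adjusted p = 0.00960). The adjusted p was 0.0858 without mutant replicate 2 and 0.670 with an estimated correlation. tpm1, a tropomyosin gene, fell by 2.29 on the log2 scale. The 15 brightest members had a median of -0.18, with 11 of them below 0. Among these, ldb3a differed by -1.25 (limma adjusted p = 0.0279), whereas myl7 at 0.0008, tnnt2a at 0.014 and myh6 at 0.88 did not pass. Genes of mitochondrial respiration, the TCA cycle and fatty acid oxidation were lower as a group: 12 of 47 fell, 0 rose and 35 did not pass, 21 fell adjusted over the list alone, and all 47 estimates were below 0. Their median log2 difference was -0.72 (camera adjusted p = 5.28e-09). The adjusted p was 0.670 with the estimated correlation between these genes, which was 0.589. slc25a4, an ADP/ATP carrier gene, fell by 2.70 ± 0.38 (SE). fry, which tests whether a list moves one way, gave an adjusted p of 0.0628 for this list and 0.0638 for the cardiomyocyte list. Genes of glycolysis and the hypoxia response were lower in balance, with 4 of 35 higher and 10 lower (6 and 13 adjusted over the list alone; median -0.63, camera adjusted p = 0.0325, and 0.670 as the adjusted p with an estimated correlation). pfkma, a phosphofructokinase gene, was at least 5.13-fold lower in mutants, where it was not well above background. The list no longer passed without WT replicate 1. Its camera adjusted p was 0.140 under a stricter filter, which tested only probes above the 60th percentile of their array on all 4 arrays. That filter left out 4 of the 10 genes that fell.

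Cell cycle genes were shifted downward by a median of -0.29, or -0.14 with median scaling and -0.07 with the unscaled deposited values (camera adjusted p = 0.0109), although limma called 0 of the 27 members over all genes and 0 over the list alone. The list's adjusted p was 0.679 with an estimated correlation, 0.0638 by fry and 0.0616 with the unscaled deposited values. The list no longer passed without WT replicate 2 (adjusted p = 0.128) or without mutant replicate 2 (adjusted p = 0.0559). Ribosomal protein genes had a median of -0.08, and limma called 0 of 67 over all genes and 0 over the list alone (camera adjusted p = 0.517). The sign of that median turned with quantile normalization (0.04), median scaling (0.07) and the unscaled deposited values (0.13), and the list passed without mutant replicate 1 (adjusted p = 0.000435). Of 14 cardiac stress genes, 2 rose and 2 fell (3 and 5 adjusted over the list alone; median -0.64, mean 0.16; camera adjusted p = 0.517, and 0.0126 as the adjusted p under the stricter filter, which removed both rises), including nppal, related to the gene of atrial natriuretic peptide, which was at least 40.1-fold higher in mutants. Of 19 genes for ion channels, gap junctions and calcium handling, 2 rose and 4 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.872). Of 29 genes of heat shock, unfolded protein and p53 responses, 2 rose and 2 fell (3 and 3 adjusted over the list alone; median 0.06, mean -0.11; camera adjusted p = 0.715).

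**Figure D2:**
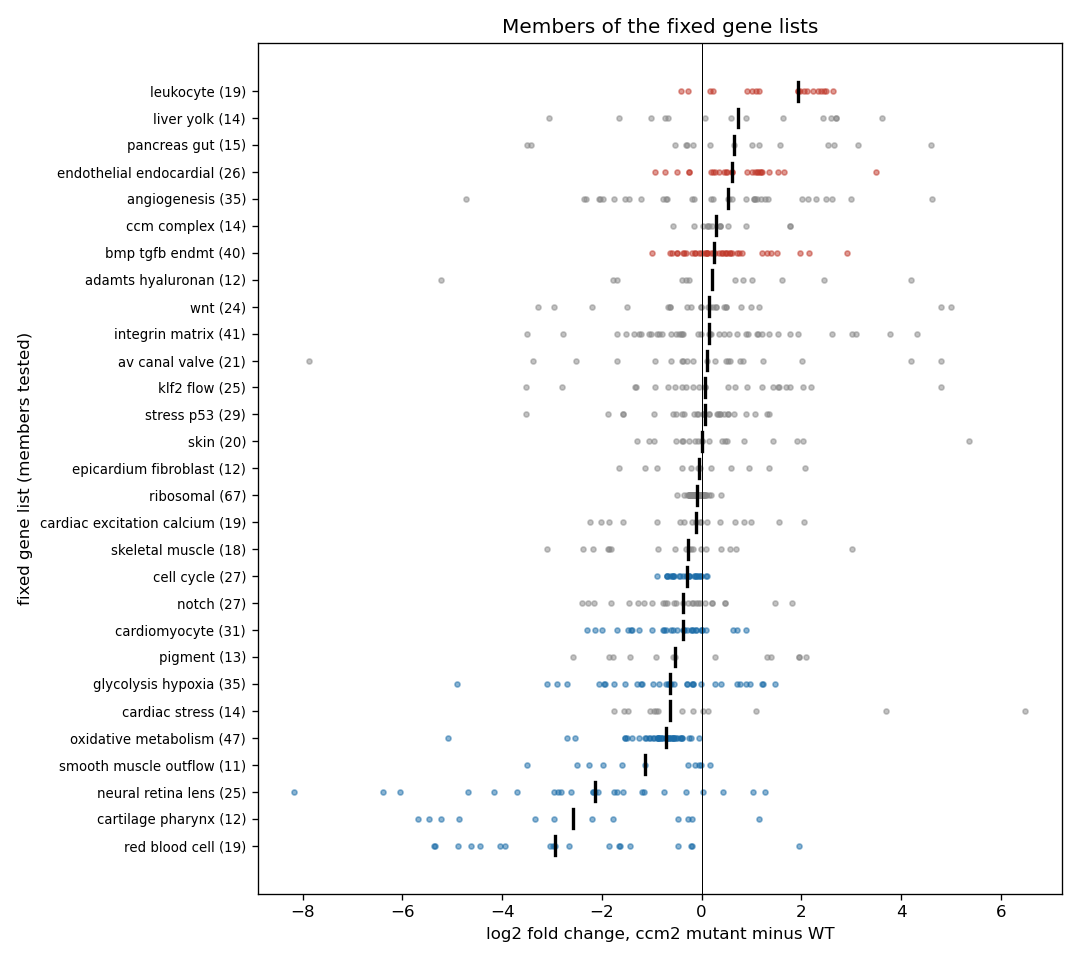
Log2 fold change (mutant minus WT, horizontal axis) of each tested member of 29 of the 30 fixed gene lists; points are genes, black ticks list medians, and colour marks lists that passed camera with a preset correlation (red higher, blue lower, grey not passed). The leukocyte list has the highest median, 1.94, and the red blood cell list the lowest, -2.95.

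Markers of other cell types, some of them from outside the heart, differed as well, and moved in different directions. Of 19 red blood cell markers, 13 fell and 1 rose (15 and 1 adjusted over the list alone; median -2.95, or -2.67 with dim genes at their bound, -1.85 under the stricter filter and -1.37 with normexp on raw median signal; camera adjusted p = 4.88e-07, and 0.670 as the adjusted p with an estimated correlation). slc4a1a, the red cell anion exchanger gene, fell by 5.37, and the globin genes hbae1.1 and hbae3 by 2.97 and 2.67, whereas alas2, a heme synthesis gene, rose by 1.95 ± 0.19 (SE). Of 19 leukocyte markers, 11 rose and 0 fell (14 and 0 adjusted over the list alone; median 1.94, or 0.79 with normexp on raw median signal; camera adjusted p = 7.15e-06, and 0.670 as the adjusted p with an estimated correlation), including the neutrophil gene mpx by 2.64 ± 0.27 (SE; its 2 other probes gave 2.33 and 2.55 and were not called) and the macrophage gene mpeg1.1 by 2.48 ± 0.20 (SE). Of 11 smooth muscle and outflow tract markers, 4 fell and 0 rose, and the same adjusted over the list alone (median -1.14, camera adjusted p = 0.0146, and 0.670 as the adjusted p with an estimated correlation). fbln5, an elastic fibre gene, fell by 3.50 and tagln, a smooth muscle gene, differed by -2.25 ± 0.20 (SE, adjusted p = 0.0117), whereas acta2 differed by -0.13 ± 0.18 (SE) and did not pass, with a sign that turned under median scaling (0.016). This list's adjusted p was 0.0589 without WT replicate 2, 0.0540 without mutant replicate 2 and 0.0638 by fry. Of 12 cartilage and pharynx markers, 7 fell and 1 rose (8 and 1 adjusted over the list alone; median -2.57, camera adjusted p = 0.000964, and 0.670 as the adjusted p with an estimated correlation), with matn4, a cartilage matrix gene, lower by a log2 difference of -4.87. Of 25 markers of the nervous system, retina and lens, 14 fell and 2 rose (18 and 2 adjusted over the list alone; median -2.14, or -1.58 with dim genes at their bound; camera adjusted p = 8.70e-06, and 0.670 as the adjusted p with an estimated correlation). The stricter filter, which needs signal above the 60th percentile on all 4 arrays, kept 6 of these 25 markers and 2 of the 14 that fell (camera adjusted p = 0.873). It therefore does not test the fall of the others.

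The remaining marker lists did not pass camera. Epicardium and fibroblast markers had 2 of 12 higher and 1 lower (3 and 2 adjusted over the list alone; median -0.05, mean 0.06, camera upward with adjusted p = 0.715). Skeletal muscle markers had 1 of 18 higher and 4 lower (1 and 6 adjusted over the list alone; camera adjusted p = 0.181, fry downward with adjusted p = 0.0350), and pigment cell markers 4 of 13 lower (4 adjusted over the list alone; camera adjusted p = 0.517). Liver and yolk markers had 1 of 14 higher (1 adjusted over the list alone; camera adjusted p = 0.517), and skin markers 3 of 20 higher (3 adjusted over the list alone; camera adjusted p = 0.645). Pancreas and gut markers had 2 of 15 higher and 2 lower (3 and 2 adjusted over the list alone; camera upward with adjusted p = 0.536, fry downward with adjusted p = 0.102). Some of the brightest markers of these lists differed between the WT arrays. The pigment gene tyrp1b had a WT SD of 3.26, ins a WT SD of 2.46 and tfa a WT SD of 1.90 on the log2 scale, and tyrp1b passed without WT replicate 1 (adjusted p = 0.0358). Liver and yolk markers passed without WT replicate 1 (adjusted p = 6.50e-06).

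**Figure D3:**
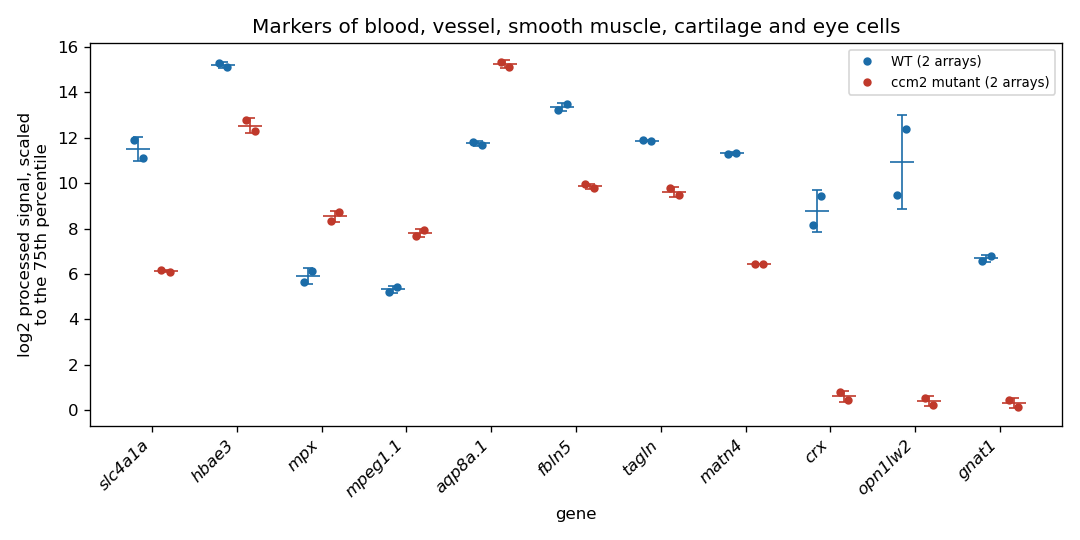
Log2 processed signal, scaled to the 75th percentile of each array, of 11 marker genes (vertical axis) in WT (blue) and ccm2 mutant (red) hearts; points are arrays, bars the mean and whiskers the SD of 2 arrays. Red cell, smooth muscle, cartilage and photoreceptor genes lie lower and mpx, mpeg1.1 and aqp8a.1 higher on both mutant arrays.

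Among named genes, 9 of the 10 largest falls, all but spp1, were in genes not well above background in mutants, and these folds are bounds. opn1lw2, a cone opsin gene, was at least 297-fold lower in mutants, opn1mw1 at least 150.03-fold, opn1sw2 at least 71.7-fold, and crx, a photoreceptor transcription factor gene, at least 66.6-fold. Both WT arrays lay far above the mutant arrays for these genes but differed from each other, with log2 signals of 9.49 and 12.40 for opn1lw2, 8.80 and 11.11 for opn1mw1, 7.47 and 10.31 for opn1sw2 and 8.14 and 9.43 for crx on WT 1 and WT 2. Without WT replicate 2 the bounds were 108-fold for opn1lw2, 67.3-fold for opn1mw1, 26.8-fold for opn1sw2 and 42.5-fold for crx, and without WT replicate 1 they were 815-fold, 334-fold, 192-fold and 104-fold. gnb3b, at least 172-fold lower, had WT signals of 8.98 and 11.33, and its bound was 76.3-fold without WT replicate 2 and 389-fold without WT replicate 1. The same form of bound applied to fbp2, a gluconeogenic enzyme gene, at least 153-fold lower, smtlb at least 55.9-fold, nptx1l at least 46.4-fold and mybpc1, a myosin-binding protein gene, at least 41.4-fold. The largest rises included lmbr1l, at least 78.8-fold higher, bcas2 at least 43.8-fold, trappc5 at least 41.9-fold, helt at least 34.5-fold, bcl3 at least 24.7-fold and vox at least 23.9-fold, all with WT signal not well above background. The other rises by the same rule were measured on all 4 arrays, apart from nppal. The tetraspanin gene cd9r rose by 6.34 ± 0.31 (SE), s100w by 6.12 ± 0.18 (SE), and cd81b, also a tetraspanin gene, from a log2 signal of 4.34 to 10.33. Of 647 called genes with more than 1 detected probe, another probe was called the same way in 433, the opposite way in 4, and no other probe was called in 210.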

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

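The alternatives using raw median signal and the filter by rank above background were chosen after the data were seen; all others were planned. The planned background correction from foreground and background columns was not run, because the deposited tables hold no background column. Of 2024 values of named genes under alternatives, 1580 kept their direction and side of the threshold, 407 lost the call, 14 gained it and 23 changed sign. Of 508 list tests, 447 kept both, 27 lost the call, 18 gained it and 16 changed sign. No value that changed sign passed the threshold on either side, and 0 of the called genes shared with any alternative changed sign. Signal over background limits the dim genes, whose folds are bounds.

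Some list medians moved by more than 1.5 times. With normexp on raw median signal, whose offset compresses low signals, list leukocyte had a median of 0.79, red_blood_cell -1.37, cartilage_pharynx -0.80, neural_retina_lens -0.72, smooth_muscle_outflow -0.25, glycolysis_hypoxia -0.25, cardiomyocyte -0.21 and bmp_tgfb_endmt 0.15, and all 8 kept their call. Under the stricter filter, red_blood_cell had -1.85 and kept its call, whereas glycolysis_hypoxia (-0.30) and neural_retina_lens (-0.58) lost it. With median scaling and the deposited values, bmp_tgfb_endmt had 0.40 and 0.47, cardiomyocyte -0.23 and -0.16 and cell_cycle -0.14 and -0.07, and glycolysis_hypoxia had -0.42 with the deposited values; only cell_cycle with the deposited values lost its call.

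The count of 1975 changed genes became 1118 without a filter on dim probes, where 43603 probes were tested, 3065 with a trended robust prior, 874 with the sample number as a replicate block, which leaves fewer degrees of freedom, and 3227 at an adjusted p under 0.1. Of the 874, 842 were shared with the 1975. Leaving out 1 array gave 0 to 567 genes, where the lone sample is assumed to vary like the other group. The count of 1828 genes changed at least 2-fold became 1118 without the filter, 874 with the replicate block and 1012 with normexp on raw median signal. Under the stricter filter it was 1055. That filter tested 7891 genes and left out 943 of the 1975, which had no probe above the 60th percentile on all 4 arrays. Such genes need not be dim, since 1438 of the 1975 were well above background on all 4 arrays. The count of 1828 also fell whichever array was left out. The 11 lists became 0 with an estimated correlation (13 by fry) and 7 to 13 without 1 array. The cause was not tested where none is given.

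Adjusted p-values of lists whose direction turned in some setting were as follows; the ranges without 1 array span all 4 arrays, and their ends of 0.000435 and 6.50e-06 come from arrays without which the direction did not turn. Without the filter, list cardiac_excitation_calcium had 0.839. By fry, list cardiac_stress had 0.302, list stress_p53 0.975 and list pancreas_gut 0.102. For list ribosomal, quantile normalization gave 0.596, the deposited values 0.938 and normexp 0.520. Without 1 array, list av_canal_valve had 0.542 to 0.988, list cardiac_excitation_calcium 0.549 to 0.978, list stress_p53 0.499 to 0.910, list ribosomal 0.000435 to 0.885, list liver_yolk 6.50e-06 to 0.547, list skin 0.0696 to 0.693 and list pigment 0.0673 to 0.559. The cause was not tested.

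Log2 differences of genes whose sign turned were as follows. Under median scaling, acta2 had 0.016 and desma 0.14. With the deposited values, acta2 had 0.081, ckma 0.044, desma 0.20 and stk24b 0.057. For desma, quantile normalization gave 0.12 and normexp 0.073. Without 1 array, the range was -0.25 to 0.22 for desma, -0.17 to 3.32 for ins, -0.39 to 0.40 for krt4, -0.15 to 0.44 for krt8, -0.094 to 0.48 for krt94, -0.36 to 0.78 for map3k3, -0.0086 to 0.061 for rap1aa, -0.26 to 1.45 for rbp4, -0.38 to 0.066 for stk24b, -7.69e-05 to 0.31 for stk25b, -1.28 to 1.40 for tfa and -0.36 to 4.25 for tyrp1b. The cause was not tested.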

Other observations

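All tests in this part except the splits of the arrays were chosen after the results they bear on were seen, and some of their criteria were revised after a first run. The genes of the next paragraph were also chosen after their values were seen.

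The genes ranked here were well above background on all 4 arrays, and clone names were left out. Each had 1 detected probe, or another probe called the same way and none called the opposite way. Among these genes, the largest falls were in htra1a, a secreted protease gene, at -7.03 ± 0.32 on the log2 scale (SE), angptl7 at -6.85 ± 0.19 and loxa, a lysyl oxidase gene, at -6.07 ± 0.19. Other falls included abi3bpb at -5.63 ± 0.20 and the immediate early gene egr3 at -5.46 ± 0.28. The largest rises after cd9r, s100w and cd81b were in cyp8b1.3 at 5.78 ± 0.18, ptprt at 5.39 ± 0.30 and ddit4, a stress-responsive gene, at 5.30 ± 0.29 (SE for each). The bone morphogenetic protein genes bmp2a and bmp2b rose by 1.98 ± 0.22 and 1.52 ± 0.20, beside a description of the mutant samples that mentions Bmp2b overexpression, which the labels do not settle.

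Cone photoreceptor genes were higher in both WT pools: of 33 tested cone and rod markers, 21 (63.6%) were lower in mutants, as were 21 of 31 inner retina markers (median -2.17; 2 rose, sncga by 4.18 and elavl4 by 1.28), so carried-over retinal tissue may have contributed. The 17 cone genes that fell and were well above background on both WT arrays were higher on WT 2 than on WT 1 by a median of 2.31 on the log2 scale, 14 of them by over 1, against a median of 0.04 for 160 level-matched genes lower in mutants, a difference within 1 genotype that uneven carry-over could give. Both sets were chosen by their call, which favours genes whose WT arrays agree. Whatever their call, 170 level-matched genes had a median of -0.02 and an SD of 0.40. Of all 25 tested cone genes, 18 lay over 1 log2 unit higher on WT 2 and 0 on WT 1. The SD of the 17 cone genes was 1.06, against 0.34 for the 160 matched genes. This argues against 1 common ratio for all 17, although the SD was 0.60 without the 2 lowest, rom1a and gngt2a. Whole eyes would also bring lens and pigment epithelium transcripts, and it goes against them that 25 of 35 lens markers on the array were too dim to test, with a median WT 2 signal of 0.86 for all 35 against 7.21 for 31 cone markers, and that the 10 tested had a median difference of -0.19 with 0 lower; yet 4 of the 35, cryba1b, cryba2a, crybb1 and crygmxl2, were well above background on WT 2 and not in mutants, and no eye sample gave the lens level to expect. The 13 tested of 17 pigment epithelium markers had a median of 0.35 with 2 lower, but 6 are also pigment cell markers and 8 lay over 1 log2 unit higher on WT 1 than on WT 2 (rpe65a at 8.45 and 4.05), opposite to the cone genes, so neither list decides, and eye or retinal tissue of varying makeup and an effect of the genotype cannot be told apart, because marker levels do not show where the cells lay.

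Some probes gave signal in 1 group only. A sequence difference under a single probe could give this where the mutant and WT stocks differ. Only such probes with a log2 change of at least 4 were examined, in 29 higher and 88 lower genes. The comparison genes measured on 4 arrays were taken at a lower cut, at least 4-fold, so the 2 selections are not alike. Of 15 genes with such a higher probe and another detected probe, the other probes all changed by under 1 log2 unit in 4 (26.7%, exact 95% interval 7.79% to 55.1%), hspbp1, jade3, mrpl43 and smox. This rule left out ttc14, where the 1 other probe went the opposite way (-1.09 against 4.94). It also left out gsr, whose brightest other probe changed by 0.69 against 6.07, although 1 of its 3 others was called higher. The share may thus be too low. The share was 8 of 101 (7.92%) for higher genes with a change of at least 4-fold measured on 4 arrays. A sequence difference therefore stays open for higher probes. For lower probes the share was 0 of 42 (0%, exact 95% interval up to 8.41%), against 9 of 100 on 4 arrays. The interval takes genes as independent, although the 42 include photoreceptor genes such as crx, gnb3b, opn1mw1 and rom1a, whose falls may share a source. The share stays 0 without them, over fewer genes and thus with a wider interval. This argues against a sequence difference as the general cause for lower genes past that cut with a second detected probe. Lower genes without one were not tested, and smaller falls were not examined. Of the named higher genes in this set, lmbr1l, bcas2, trappc5, helt, bcl3, nppal and angpt2b had no second detected probe, so it stays open for each.

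The fall of oxidative metabolism genes could come from fewer cardiomyocytes in the mutant tissue. A lower share alone would raise the markers of all other heart cell types alike. The medians of the 5 such lists spanned 4.89, from -2.95 (red blood cells) to 1.94 (leukocytes), more than in any shuffle of members between lists. Without the blood cell lists they spanned 1.75 (permutation p = 0.000930, genes taken as independent). These medians were known before this form of the test was written, so the shuffle could not come out otherwise and does not decide. Members of a list were also correlated, by an estimated 0.32 for red blood cell and 0.25 for leukocyte markers. The values show only that these lists did not move alike. A lower share stays open, together with changes in other types. The shuffle was the 4th form of this test, and the outcome depended on the form. In the others the whole cardiomyocyte list lay above the oxidative list by 0.34 ± 0.18 (SE of the difference of medians, over genes), which left the question open. Its 15 brightest genes lay above it by 0.54 ± 0.13, and endothelial above smooth muscle markers by 1.75 ± 0.75. These 2 differences go against a lower share only if genes are taken as independent, since the SEs do not measure the spread between arrays. Ribosomal genes, which were brighter, lay above the oxidative list by 0.64 ± 0.07, whereas scaling or compression of bright probes would lower both. This SE is also over genes taken as independent, although the estimated correlations were 0.926 (ribosomal) and 0.589 (oxidative). The difference therefore argues against scaling or compression on these 4 arrays, and its SE does not measure replication.

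The 4 arrays can be split into pairs in 3 ways, too few for a share under 0.05. The real split gave 4294 changed probes, was the 1 split with as many, and the highest of the others gave 0 by limma, with 361 and 266 probes at an unadjusted p under 0.05.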
